A study of Mus musculus with 13 samples.

How the data were processed

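Single cells of the mouse small intestine were measured in 13 CEL-seq libraries, a method that tags the 3' ends of transcripts with a cell barcode and a molecular barcode. Per the labels, the mice carried an Lgr5-driven inducible Cre and a YFP reporter, so that tamoxifen marks the Lgr5+ stem cells and their later offspring (traced cells). The groups were 5-day traced cells (5 libraries), 3-week traced CD24+ cells (1), a library labelled 3-week non-traced CD24+ cells (1), 8-week traced CD24+ cells (3), 8-week traced cells without the CD24 gate (1) and 8-week non-traced CD24+ cells (2). CD24 is a surface protein used here as a sorting gate.

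The deposited values are expected counts of transcripts per gene and cell, corrected for random collisions of 256 molecular barcodes and not scaled between cells. This was read from the values: each one is the transform of a whole number of molecular barcodes, and 145 of the 3172205 values above 0 were saturated at a deposited value of 1597, so the most abundant transcripts of a few cells are underestimates. The submitters' processing notes name BWA 0.6.2-r126 and mm10; gene models and read filters are not stated there. Each library held 96 barcodes, and the union of the files held 16204 genes. A combined table of 672 cells in 7 sets was compared with the per-library values, and each set held the values of 1 library to within 0.001. It was used in no test, but its names divide the 8-week CD24+ libraries into a first round (replicate 1 of each group) and a second round (the others), which served as batches. The cells of the library labelled 3-week non-traced CD24+ carry a name there that contains YFP and no CD24; the label was kept, the conflict is stated where the library is used, and no tested comparison includes it.

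Barcodes with at least 3000 transcripts without spike-in RNA were kept, which left 892 cells of 1248 and removed 356. Each count was divided at random into 2 binomial parts with probability 0.5. The first part made the clusters, so that comparisons between classes could use the other part. Clusters were found with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 principal components, 10 neighbours, resolution 1) and named by fixed marker lists from differences within libraries: at least 3 markers raised by 0.25 on the scale of log2(transcripts per 10000 + 1) and 1 marker among the 10 leading genes. Clusters with over 85% of cells from 1 library stayed unnamed. The choice of variable genes within libraries, the naming rule and this limit were set after the data had been examined, and 2 ways of clustering were tried. Classes are called Paneth-like, goblet-like, tuft-like, enteroendocrine-like, enterocyte-like, stem-like and proliferating-like, since no marker protein was measured. No doublet detection was run.

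The library was the replicate. Counts were summed over the cells of a class or of a library, rounded, and tested with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr, Benjamini-Hochberg threshold 0.05) in R 4.3.3; libraries with under 3 cells of the class were left out of that comparison. Levels are CPM, the share of a sum's transcripts in the usual scaling of edgeR. Comparisons of classes within the 5-day libraries used the part of the counts that the clusters did not use, with the library as a block. The replicate numbers of different groups were not taken to pair the libraries: residual correlations between equal numbers were 0.071 and 0.027 for traced against non-traced Paneth-like cells and 0.085 and 0.126 for all cells. With 2 non-traced libraries each correlation mirrors the other. A replicate block was tried only as an alternative, and the batch that replicate 1 of both groups shares was tried as a batch block. For traced against non-traced cells the replicate block left out traced replicate 3, whose number no non-traced library has. Gene lists fixed before the data were examined were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, and with fry. Of the 28 endoplasmic reticulum folding genes in the files, 26 could be tested in the 8-week Paneth-like cells; the mitochondrially encoded list had 0 genes in the files, so it was not used here. Shares of cells were compared by an exact two-sided permutation test over libraries. Groups of 1 library were described with exact Poisson intervals and no test. Confidence intervals are at 95%. Those of counts and shares, like the floors of 3 counts over a group at 0, cover counting error only. The interval of the Paneth-like minus stem-like list mean is a t interval over libraries, and those of ratios come from redrawing genes, or cells for Cd24a, and cover no spread between libraries.

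Genes named were, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold with at least 20 CPM in the higher group and no overlap between groups (for comparisons within a library, the same direction in every library), and up to 4 members per fixed list with the smallest p. For groups of 1 library they were the same genes and the 10 largest folds each way. Some genes that met this rule are not reported here. Positions are those of GENCODE vM21 on GRCm38; 234 of 245 named genes were found in it, each on the chromosome that the deposited gene name gives.

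The procedure was tested on simulated data made from the same libraries. In the 8-week Paneth-like cells, traced against non-traced, 26.3% of genes changed 2-fold and 93% of those changed 4-fold were recovered, and 3.3% of calls were unchanged genes. For 8-week against 5-day Paneth-like cells these values were 54.9%, 99% and 5.8%. All libraries were drawn once, from 1 pooled profile with the fitted dispersions and independent genes. The simulated data hold no batch, no class mix and no correlation between genes, so errors in the real data can be more frequent. The alternatives tried were RLE factors, DESeq2 1.42.0, no filter on low counts, library sizes without Paneth antimicrobial genes, uncorrected barcode counts, minima of 1500 and 5000 transcripts per cell, resolutions 0.5 and 2, a class by marker share (at least 5% of transcripts), variable genes over all cells, replicate and batch blocks, single Paneth-like clusters, and leaving out each replicate. Comparisons of tuft-like cells, of stem-like cells between times, and of the Paneth-like minus stem-like difference between times were added after the data had been examined.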

Results

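The 13 libraries held between 421675 (library labelled 3-week non-traced CD24+) and 1385266 transcripts (8-week traced CD24+ replicate 1), and the 892 kept cells had library medians of 5412 to 14458 transcripts. Spike-in RNA took 1.31% to 16.6% of a library's counts, the highest share in the library labelled 3-week non-traced CD24+. The 5-day libraries held 646976 to 821958 transcripts, the 8-week traced CD24+ libraries 658918 to 1385266, and the 8-week non-traced CD24+ libraries 716008 and 1172368. Xist, the X-inactivation transcript of female cells, stood at 0 to 0.0134 per 10000 transcripts in the 5-day libraries and at 0.813 to 1.74 in all 8 later libraries. The Y-linked Ddx3y stood at 0.197 to 0.424 in the 5-day libraries and at 0 in the later ones. The sex of the mice therefore differed between the 5-day and the later libraries.

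The make-up of the sorted populations was compared first. Tuft-like cells, chemosensory cells marked by Dclk1 and Trpm5, made up 19.7% ± 2.21 (SD, n = 3) of the 8-week traced CD24+ cells and 48.4% ± 1.12 (n = 2) of the non-traced CD24+ cells. Stem-like cells (14.4% ± 4.06 against 3.37% ± 0.281), proliferating-like cells (14.8% ± 7.31 against 1.59% ± 2.24) and goblet-like cells (7.96% ± 4.39 against 0.595% ± 0.842) had higher shares among the traced cells. Paneth-like cells, the antimicrobial cells of the crypt base, made up 15.2% ± 4.10 of the traced and 18.3% ± 1.12 of the non-traced cells. Enteroendocrine-like cells made up 25.2% ± 3.73 and 20.2% ± 1.68. In each of these classes except the Paneth-like the libraries of the 2 groups did not overlap, but the exact permutation test gave p = 0.2, the smallest that 3 against 2 libraries allow; for Paneth-like cells it gave p = 0.4. At resolution 2 the Paneth-like difference was 1.56 percentage points the other way, and with at least 5000 transcripts per cell the enteroendocrine-like difference turned to -1.96.

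Between 5-day traced cells and 8-week traced CD24+ cells, tuft-like cells went from 0 of 332 cells to 19.7%, enteroendocrine-like cells from 1.82% ± 1.28 (n = 5) to 25.2%, and enterocyte-like cells from 10.1% ± 5.26 to 0 of 221 cells. Paneth-like cells made up 6.49% ± 4.88 of the 5-day cells and 15.2% of the 8-week traced CD24+ cells. The exact permutation test gave p = 0.0357 (adjusted 0.0833) for the tuft-like, enteroendocrine-like and enterocyte-like shares, the smallest that 3 against 5 libraries allow, and p = 0.0714 (adjusted 0.125) for the Paneth-like share, so no share passed the adjusted threshold. Proliferating-like cells made up 22.6% ± 3.38 of the 5-day cells and 14.8% of the 8-week ones (exact permutation p = 0.143), a difference that turned to 27.3 percentage points the other way with at least 1500 transcripts per cell and to 12.6 with at least 5000 (exact permutation p = 0.0357 for each), so its direction is left open. The CD24 gate was used for these 8-week libraries and not at 5 days, and the test does not separate time from gate. In the 8-week traced library without the gate (80 cells, no test) tuft-like cells made up 3.75%, enteroendocrine-like 6.25%, enterocyte-like 6.25% and Paneth-like 3.75%, nearer to the 5-day than to the gated 8-week shares. In 5-day replicate 4, 43 of 68 cells stayed unnamed, 41 of them in a cluster found in that library alone.

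**Figure D1:**
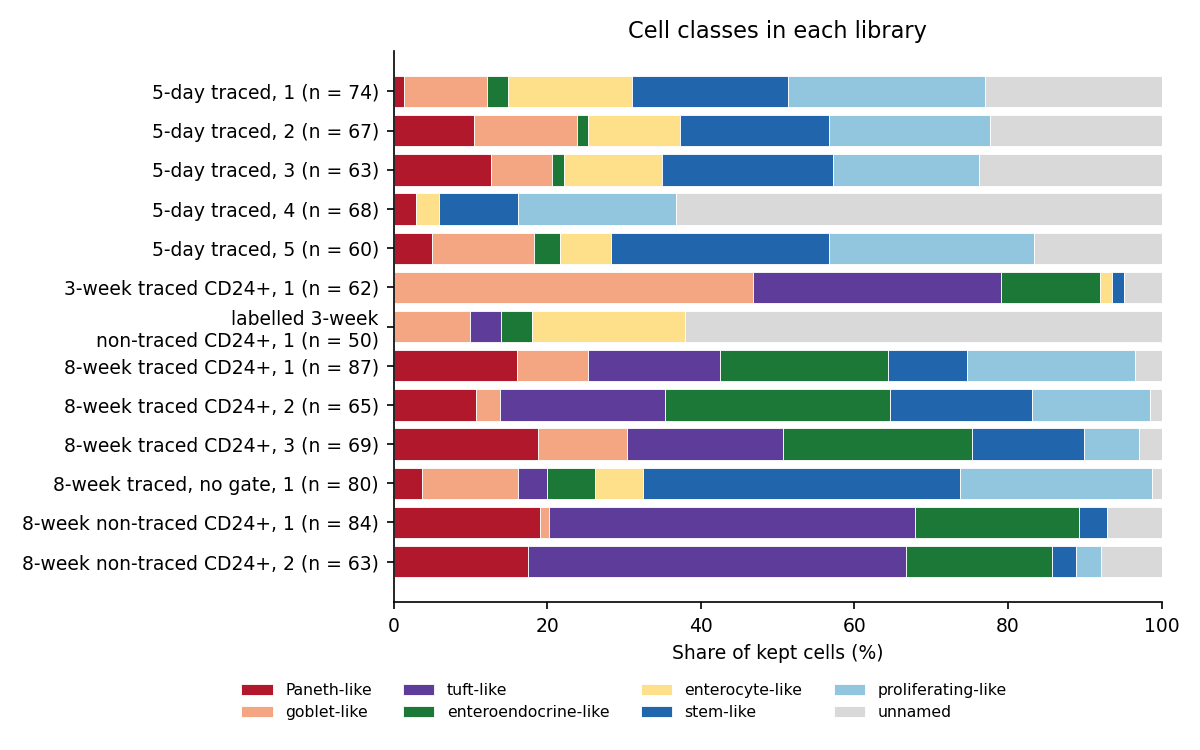
Share of kept cells (%) in each of 8 classes, unnamed included, for each of the 13 libraries, with the number of kept cells beside the library's name. Tuft-like cells took 47.6% and 49.2% of the non-traced 8-week libraries and 17.2% to 21.5% of the traced CD24+ ones.

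Whether traced Paneth-like cells of 8 weeks differ from non-traced ones of the same gate was tested in 3 traced (14, 7 and 13 cells) against 2 non-traced libraries (16 and 11 cells). Among the rises were the pentraxins Mptx2 (chromosome 1, 173274382 to 173277777), at 16608 ± 5063 CPM (SD, n = 3) in traced and 5918 ± 626 CPM (n = 2) in non-traced cells, and Mptx1 (1.33 on the log2 scale), the lipase-related Pnliprp2 (1.37) and the alpha-defensin Defa23 (1.32). The secretory granule protein Chgb (1.55), Scgb2b19 (1.41) and the lysosomal protease Lgmn (1.34) also rose. Chgb is on the enteroendocrine marker list, and no doublet detection was run, so a source in enteroendocrine-like cells was not excluded. Among the falls were 2 enzymes of cholesterol synthesis, Hmgcs1 (-1.74) and Fdps (-1.81), and Cd177 (-3.48), Anxa2 (-3.10), Ms4a8a (-3.05), AW112010 (-2.38), Gm10548 (-2.25), Prss32 (-1.93) and the creatine kinase Ckmt1 (-1.59). Gm21002, an abundant transcript whose function is not stated here, was at 3466 CPM in traced and 9907 CPM in non-traced cells (-1.51). It is not on the Paneth list. With the non-traced libraries pooled it stood at 9233 CPM in Paneth-like and 103 CPM in tuft-like cells. Cd74, the chaperone of MHC class II molecules, fell by 1.45.

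Of 2940 genes tested with edgeR, 24 passed (11 higher, 13 lower), and 22.9% had no overlap between the groups, where chance gives 20%. Those named had adjusted p from 0.0152 for Cd177, AW112010 and Hmgcs1 to 0.0461 for Ckmt1. Of the 26 Paneth antimicrobial and granule genes tested, 2 rose (Pnliprp2 and Defa23) and 24 did not pass; adjusted over the list alone, 12 were higher and 4 lower. The list was called higher by camera (adjusted p = 9.04e-07), a call lost with an estimated correlation (adjusted p = 0.72 with an estimated correlation). Reg3g, a lectin against bacteria, was at 876 CPM in traced and 2844 CPM in non-traced cells (adjusted p = 0.0841). Ribosomal protein genes, 0 of 77 past the test, were called lower as a list (adjusted p = 9.04e-07, and adjusted p = 0.72 with an estimated correlation), as were the nuclear oxidative phosphorylation genes (0 of 70, adjusted p = 0.0113, and 0.72 with an estimated correlation). Stem genes were called higher (0 of 5, adjusted p = 0.0469, and 0.72 with an estimated correlation). None of the 26 endoplasmic reticulum folding genes passed. The count of calls depended on the library left out: without traced replicate 3 there were 0, at a median ratio of 0.973 to the reported folds, without traced replicate 1 12, and without non-traced replicate 2 79. Library sizes without Paneth antimicrobial genes gave 28 calls (8 higher, 20 lower). DESeq2 called 16 genes (13 higher, 3 lower), 8 of them among the 24, while batch as a block gave 40 (16 higher, 24 lower), 23 of them shared. The count was 0 with at least 1500 transcripts per cell and with a replicate block, 1 at resolution 2, 13 by marker share, 11 in the larger Paneth-like cluster and 58 with no filter on low counts. The replicate block used the same libraries as the fit without traced replicate 3, so its 0 is not a separate check and does not speak to pairing.

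**Figure D2:**
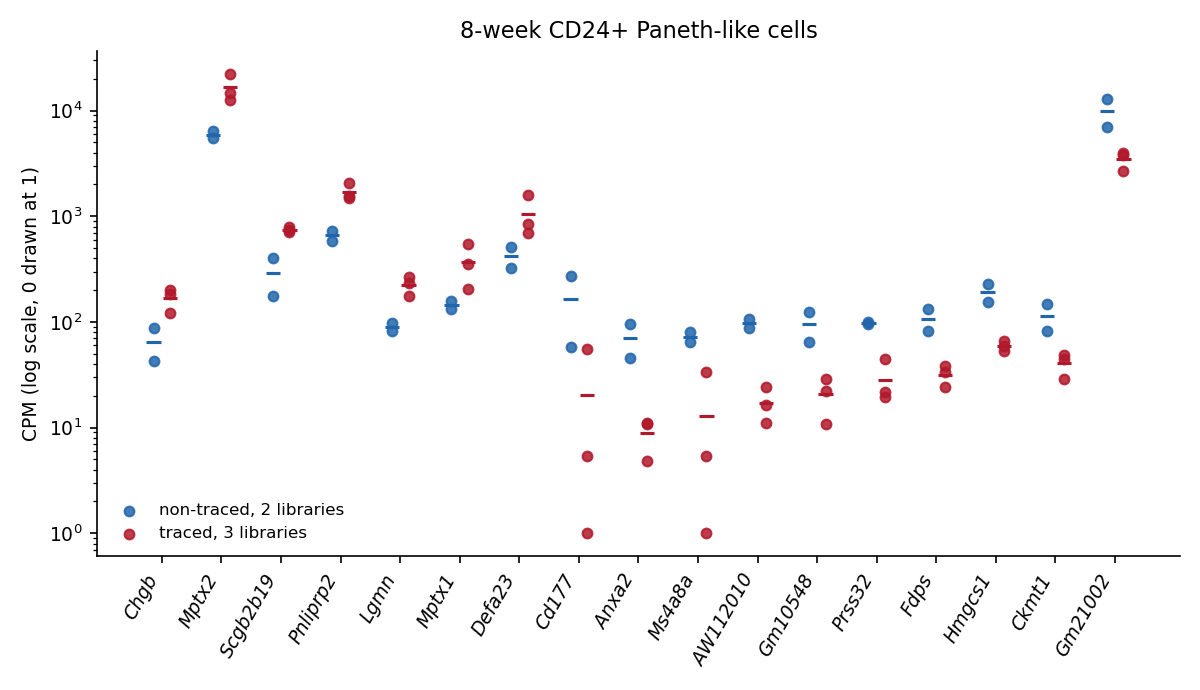
Levels in CPM (log scale, 0 drawn at 1) of named genes in 8-week CD24+ Paneth-like cells, each point a library and each bar the mean of 3 traced or 2 non-traced libraries. For Mptx2 the means were 16608 and 5918 CPM, and in Cd177 and Ms4a8a the fall includes a traced library at 0.

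Summed over all cells, traced against non-traced CD24+ cells of 8 weeks differed in tuft, stem and cell cycle genes. All 9 tuft genes tested fell in the traced cells, among them the taste transduction channel Trpm5 (chromosome 7, 143069153 to 143094642), at 197 CPM in traced and 569 CPM in non-traced libraries (-1.53, SE 0.16, n = 3 and 2), the actin binding Avil (-1.37), Dclk1 (-1.24) and the tuft cell transcription factor Pou2f3 (-1.37). The tuft-like share moved with them, at 19.7% against 48.4% of cells. Of 8 stem genes 4 rose: Gkn3 (2.98), Slc12a2 (0.99), the Wnt pathway feedback gene Axin2 (1.11) and Rgmb (1.16). Of 27 S and G2/M phase genes 6 rose, including the kinase Cdk1 (1.58), the replication factors Mcm5 (1.14) and Mcm7 (0.87), and Hmgb2 (1.11), with 25 higher adjusted over the list alone. The stem-like (14.4% against 3.37%) and proliferating-like (14.8% against 1.59%) shares moved with them. Of 15 Wnt target genes Sp5 (2.31), Axin2 and Ccnd2 (0.82) rose.

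Neurog3, the transcription factor that starts the enteroendocrine programme, was at 129 CPM in traced and 12.3 CPM in non-traced libraries (3.20). Chga, a granule protein of endocrine cells, rose by 1.71 and the hormone gene Sct fell by 1.30. These were the 3 of 14 enteroendocrine genes that passed. Cell numbers moved with them. The enteroendocrine-like cluster led by Neurog3 held 6, 6 and 6 traced against 2 and 2 non-traced cells. The one led by Chgb and Chga held 9, 7 and 6 against 2 and 3. The one with Sct among its leading genes held 4, 6 and 5 against 14 and 7. Igfbp2, which binds insulin-like growth factors, was at 58.5 CPM in traced libraries and at 0 in non-traced ones, at least 35.5-fold higher. Clu (3.44), the Wnt receptor Fzd2 (2.51), Ooep (2.46), the transcription factor Foxq1 (2.42) and Dpysl5 (2.24) rose too, as did Afp (5.63). Of the counts, 1 cell held 40.6% for Afp, 36.1% for Hhex, 27.8% for Ooep and 26% for Igfbp2. Hhex (-3.46), Cpne5 (-3.39), Gcnt1 (-2.68), Gm21002 (-2.60), Trib2 (-2.58), Fam167a (-2.54), Cd37 (-2.53), Fcna (-2.46) and Ptprc, the leukocyte antigen CD45 (-2.46), fell, and so did Rhox8 (-2.77), with 50.1% of its counts in 1 cell. The cells with the most counts of Cpne5, Gcnt1, Trib2, Cd37, Fcna and Ptprc were tuft-like. Of 26 Paneth antimicrobial genes Defa20 (-1.91) and Defa5 (-0.99) fell.

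In all, 371 of 8762 genes passed with edgeR (137 higher, 234 lower), and 34.8% had no overlap between the groups, where chance gives 20%. The count was 357 with batch as a block, 321 of them shared. Camera called the tuft genes lower (adjusted p = 9.67e-12, and 0.293 with an estimated correlation), the S and G2/M phase genes higher (9.67e-12, and 0.466 with an estimated correlation) and the stem genes higher (8.05e-06, and 0.293 with an estimated correlation). It also called the Wnt targets higher (0.00996, and 0.466 with an estimated correlation), the ribosomal protein genes higher (3.37e-06, with 0 of 80 members past the test, and 0.631 with an estimated correlation) and the Paneth list lower (0.0275, and 0.743 with an estimated correlation). With fry, the tuft genes (adjusted p = 0.0161) and the stem genes (adjusted p = 0.0453) moved on balance 1 way. The other lists that camera called did not pass with fry. Its adjusted p was 0.136 each for the S and G2/M phase, Wnt target and ribosomal protein genes, and 0.541 for the Paneth list. DESeq2 called 200 genes, 196 of them shared, no filter on low counts gave 811, and the count without non-traced replicate 1 was 55, without non-traced replicate 2 153 and without traced replicate 1 148.

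Since tuft-like cells were so unequal in number, their own profile was compared as well (15, 14 and 14 traced against 40 and 31 non-traced cells), a comparison added after the shares had been seen. Of 3138 genes 1 passed with edgeR: the alpha-defensin Defa21, with 2 transcripts (6.05 CPM) in traced and 82 (205 CPM) in non-traced tuft-like cells (adjusted p = 0.0381). Defa21 is on the Paneth marker list, and no doublet detection was run. Whether these transcripts came from Paneth-like cells was not tested, so they may not belong to the tuft-like profile. The tuft genes were close: Dclk1 stood at 3126 CPM in traced and 2642 CPM in non-traced cells, Rgs13 at 2359 and 1999, Trpm5 at 1771 and 1958, and 0 of 9 passed. At an unadjusted p under 0.05 there were 148 genes, and 17.9% of genes had no overlap between the groups, where chance gives 20%. DESeq2 called 0 genes, and leaving out 1 library gave 0 to 11, 0 without traced replicate 1 and 0 without traced replicate 3.

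The Paneth-like cells of 5-day tracing were set against stem-like cells of the same libraries, to describe what the young lineage already expresses (replicates 2, 3 and 5, with 7, 8 and 3 Paneth-like and 13, 14 and 17 stem-like cells). The class was named by its raised Paneth markers, so the rise of the Paneth list (23 of 23 tested) restates that choice, and its levels describe the class without testing it. The alpha-defensin Defa5 (chromosome 8, 21297439 to 21298375) stood at 22918 CPM in Paneth-like cells and at 49.2 CPM in stem-like cells (8.87, SE 0.31, n = 3 pairs), and the angiogenin Ang4 at 19049 CPM against 9 transcripts. Defa21 stood at 5616 CPM against 1 transcript, and Defa26 at 8150 CPM against 3. Mptx1 (at least 148-fold), Gm15292 (at least 124-fold), Defa6 (at least 116-fold), Gm14850 (at least 80.4-fold) and Gm21498 (at least 48.3-fold) were at 0 in the stem-like cells.

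The 4 goblet genes tested were also higher than in stem-like cells: Spink4 (5.86), Ccl6 (4071 CPM against 2 transcripts), Tff3 (2.98) and the mucin Muc2 (4.33). Of 11 endoplasmic reticulum folding genes 4 rose, namely the secretory cell regulator Xbp1 (2.55), the disulphide isomerase P4hb (1.46), Ssr4 (1.47) and Sec61b (1.36), 5 adjusted over the list alone. Of 5 immediate early genes 3 rose, among them Fos (4.11) and Jun (2.64), with Atf3 at least 36.7-fold higher. Reg4, a secreted lectin, was at 4311 CPM against 33.2 CPM. The 6 genes that fell were Tmem14c (-1.80), Dmbt1 (-1.69), Lgals2 (-0.95), the ATP synthase subunit Atp5g1 (-0.77), Txn1 (-0.76) and Pigr (-0.46). The stem genes Slc12a2 and Smoc2 did not pass, at 1058 against 1267 and 409 against 392 CPM. The cluster that held the 5-day Paneth-like cells had a median of 19101 transcripts per cell. The cluster that held most 5-day stem-like cells had a median of 5515. Since no doublet detection was run, doublets of the 2 classes were not excluded as a source of these stem transcripts.

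In all, 64 of 628 genes passed with edgeR (58 higher, 6 lower). Camera called the goblet (adjusted p = 4.32e-06, and 0.157 with an estimated correlation), immediate early (4e-04, and 0.157 with an estimated correlation) and endoplasmic reticulum (0.0238, and 0.218 with an estimated correlation) lists higher, and the oxidative phosphorylation genes lower (0.00893, 1 of 61 past the test, and 0.157 with an estimated correlation). Library sizes without Paneth antimicrobial genes moved the median of all genes by -0.292 and gave 73 calls (48 higher, 25 lower), with 2 rather than 4 endoplasmic reticulum genes higher, and 7 of 76 ribosomal protein genes lower against 0. With all counts, which the clusters also used, 105 genes passed, and at 1500 transcripts per cell or resolution 0.5 the comparison gave no value.

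Against goblet-like cells of the same libraries (9, 5 and 8 cells), the other secretory class at 5 days, both classes had been named by their markers, so the rise of all 24 Paneth genes tested and the fall of 6 of 8 goblet genes restate the naming. As a description, Defa5 stood at 21335 CPM against 2 transcripts, and Defa22 (4788 CPM) and Defa21 (5224 CPM) against 1 transcript each. Gm14850 (at least 72.9-fold), Defa-rs7 (at least 64.8-fold) and Gm21498 (at least 43.7-fold) were at 0 in goblet-like cells, and Gm14851 (8.40) and Gm15284 (8.34), at 111290 and 100470 CPM, also rose. The goblet genes that were lower included the mucus proteins Fcgbp (-6.08, SE 0.32, n = 3 pairs; chromosome 7, 28071236 to 28120862) and Zg16 (-5.79) and the mucin-folding isomerase Agr2 (-3.80), and 1 goblet gene was higher. Clca3 stood at 3 transcripts against 1449 CPM. Guca2a, the gut hormone guanylin (-2.94), Anxa13 (-2.94), Tmsb10 (-2.63), Klk1 (-2.61), Slc12a8 (-2.59) and the brush border myosin Myo1a (-2.52) fell as well.

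Of 17 endoplasmic reticulum folding genes 5 were lower in Paneth-like than in goblet-like cells, including the chaperones Calr (-1.95) and Hspa5 (-1.29) and the translocon parts Ssr2 (-1.29) and Sec61g (-1.46), 7 adjusted over the list alone. Of 8 immediate early genes 4 were higher, among them Jun (1.54), Egr1 (1.79), Atf3 (1.92) and Fos (1.15). Of 75 ribosomal protein genes 4 were higher, Rps20 (0.63), Rpl12 (0.55), Rpl10a (0.55) and Rpl5 (0.54), and 0 adjusted over the list alone or with library sizes without Paneth antimicrobial genes. In all, 101 of 740 genes passed with edgeR (54 higher, 47 lower). Camera gave adjusted p = 0.00551 for the endoplasmic reticulum list, lower (0.337 with an estimated correlation). It gave 0.013 for the immediate early list (0.537 with an estimated correlation), 3.77e-05 for the ribosomal list (0.207 with an estimated correlation) and, lower, 0.00777 for oxidative phosphorylation (3 of 65 members past the test, 0.207 with an estimated correlation). DESeq2 called 45 genes (33 higher, 12 lower), all among the 101, RLE factors gave 96 (62 higher, 34 lower), a fit without the library block gave 59, and without replicate 2 there were 58; library sizes without Paneth antimicrobial genes moved the median of all genes by -0.12.

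**Figure D3:**
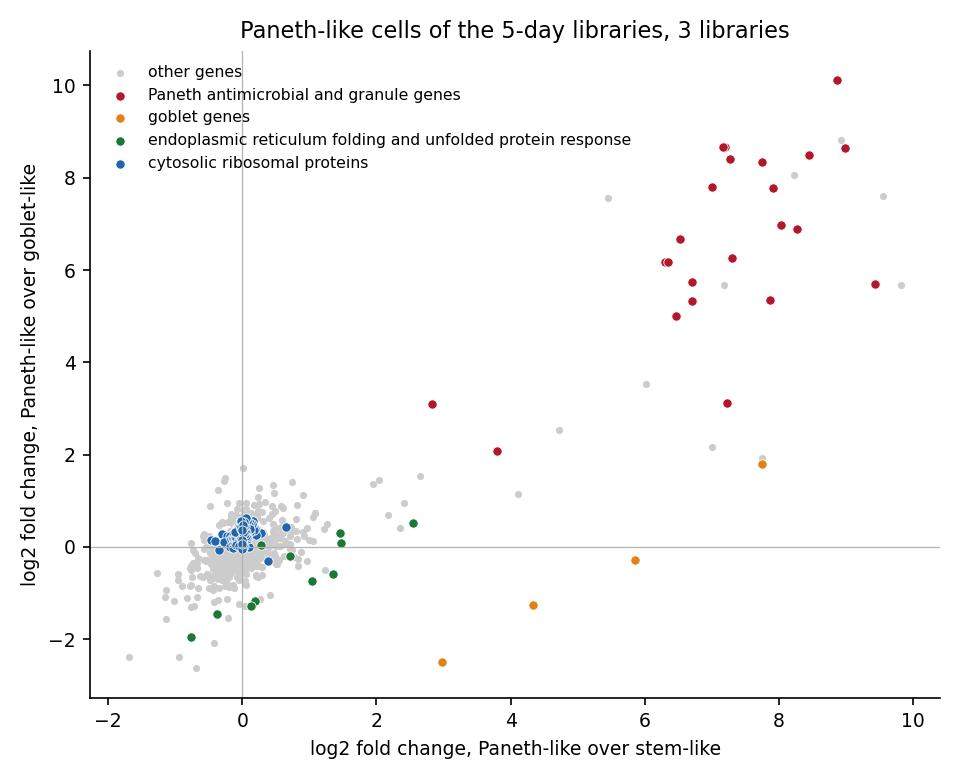
Fitted log2 fold change of Paneth-like over stem-like cells (x axis) and over goblet-like cells (y axis) for each gene tested in both, from 3 5-day libraries, with 4 fixed lists in colour; fitted values of genes at 0 in a class depend on the prior count. The Paneth antimicrobial and granule genes lie at the upper right, and of the goblet genes shown Tff3 lies at 2.98 on the x axis and below 0 on the y axis.

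How the Paneth-like profile changed with time after tracing was tested in 8-week traced CD24+ (14, 7 and 13 cells) against 5-day traced libraries (7, 8 and 3 cells). Genes of protein folding in the endoplasmic reticulum rose together: 18 of 21 tested, 19 adjusted over the list alone, among them the chaperones Hspa5 (chromosome 2, 34771970 to 34777547), at 1027 CPM at 8 weeks and 254 CPM at 5 days (2.06, SE 0.27, n = 3 and 3), and Calr (1.51), and the disulphide isomerases Pdia3 (2.04) and Pdia6 (1.53). All 7 goblet genes tested rose, including the secretory transcription factor Spdef (3.44), Agr2 (2.70), Spink4 (2.01) and Muc2 (1.41). Of 9 secretory lineage transcription factors 8 rose, with Bhlha15 (1.86), Atoh1 (1.74) and Klf4 (1.57) beside Spdef, which both lists hold. Of 25 Paneth antimicrobial genes 10 rose, including the phospholipase Pla2g2a (2.28), Defa20 (2.72) and Habp2 (1.64), and 0 fell.

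Ribosomal protein genes fell, 59 of 75 tested, with Rpl31 (-2.09), Rps26 (-1.52), Rpl3 (-1.49) and Rpl22 (-1.43), and 25 of 65 nuclear oxidative phosphorylation genes fell, among them Cox7a2l (-1.55). Immediate early genes fell too (7 of 8), with Fosb (-2.44), Egr1 (-1.65) and Atf3, which was at 447 CPM at 5 days and at 0 at 8 weeks, at least 67.3-fold lower. All 4 enterocyte absorption genes tested fell, among them Prap1 (-2.96), the fatty acid carrier Fabp2 (-1.71) and the apolipoprotein Apoa1, at 1 transcript against 171 CPM. Over all classes, Fabp1 of the same list was found in 33 of 63 (replicate 3) to 69 of 74 cells (replicate 1) of the 5-day libraries. These falls may therefore not be particular to Paneth-like cells. Other large rises were Gm7849 (4.66), Gm15308 (4.24), the nuclear RNA Malat1 (3.77), Scgb2b19 (3.55), the calcium pump Atp2a3 (3.24), Chgb (3.15), the chemokine Ccl9 (3.03), Gm10104 (2.96) and Yipf5 (2.85). Gm7849 is on no fixed list but was among the leading genes of the larger Paneth-like cluster. Chgb is on the enteroendocrine list, and a source in enteroendocrine-like cells was not excluded. Falls outside the lists were Gm11517 (-5.21), Gm4832 (-3.42), Slx1b (-3.23), Thbs1 (-3.13), Gm6548 (-2.67) and the carboxylesterase Ces2e, at 2 transcripts against 192 CPM. In stem-like cells, compared over 3 8-week and all 5 5-day libraries, Gm11517 (-4.40), Gm4832 (-3.73), Ces2e (-3.44), Gm6548 (-3.27) and Slx1b (-2.06) fell and Malat1 (2.30) rose as well.

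With edgeR 503 of 1162 genes passed (250 higher, 253 lower), and 612 genes (52.7%) had no overlap between the groups, where chance gives 10%. Camera gave adjusted p = 2.03e-06 for the endoplasmic reticulum list (0.113 with an estimated correlation), 0.000253 for goblet genes (0.123 with an estimated correlation), 0.000508 for secretory transcription factors (0.113 with an estimated correlation), 0.0081 for the Paneth list (0.455 with an estimated correlation), and, lower, 3.02e-15 for ribosomal proteins (0.162 with an estimated correlation). Also lower were oxidative phosphorylation, with adjusted p = 7.85e-07 (0.149 with an estimated correlation), and the lists with 0.000452 for immediate early genes (0.149 with an estimated correlation) and 0.000765 for enterocyte genes (0.162 with an estimated correlation). Library sizes without Paneth antimicrobial genes moved the median of all genes by 0.129; immediate early genes were then lower in 4 of 8 rather than 7, and oxidative phosphorylation genes lower in 16 and higher in 1 rather than 25 and 0. The groups also differed in gate and sex, and all 5-day Paneth-like cells lay in the smaller of 2 Paneth-like clusters, while most 8-week ones lay in the larger; within the smaller cluster, where 2 8-week libraries of 3 cells each were left, 22 of 707 genes passed (6 higher, 16 lower).

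**Figure D4:**
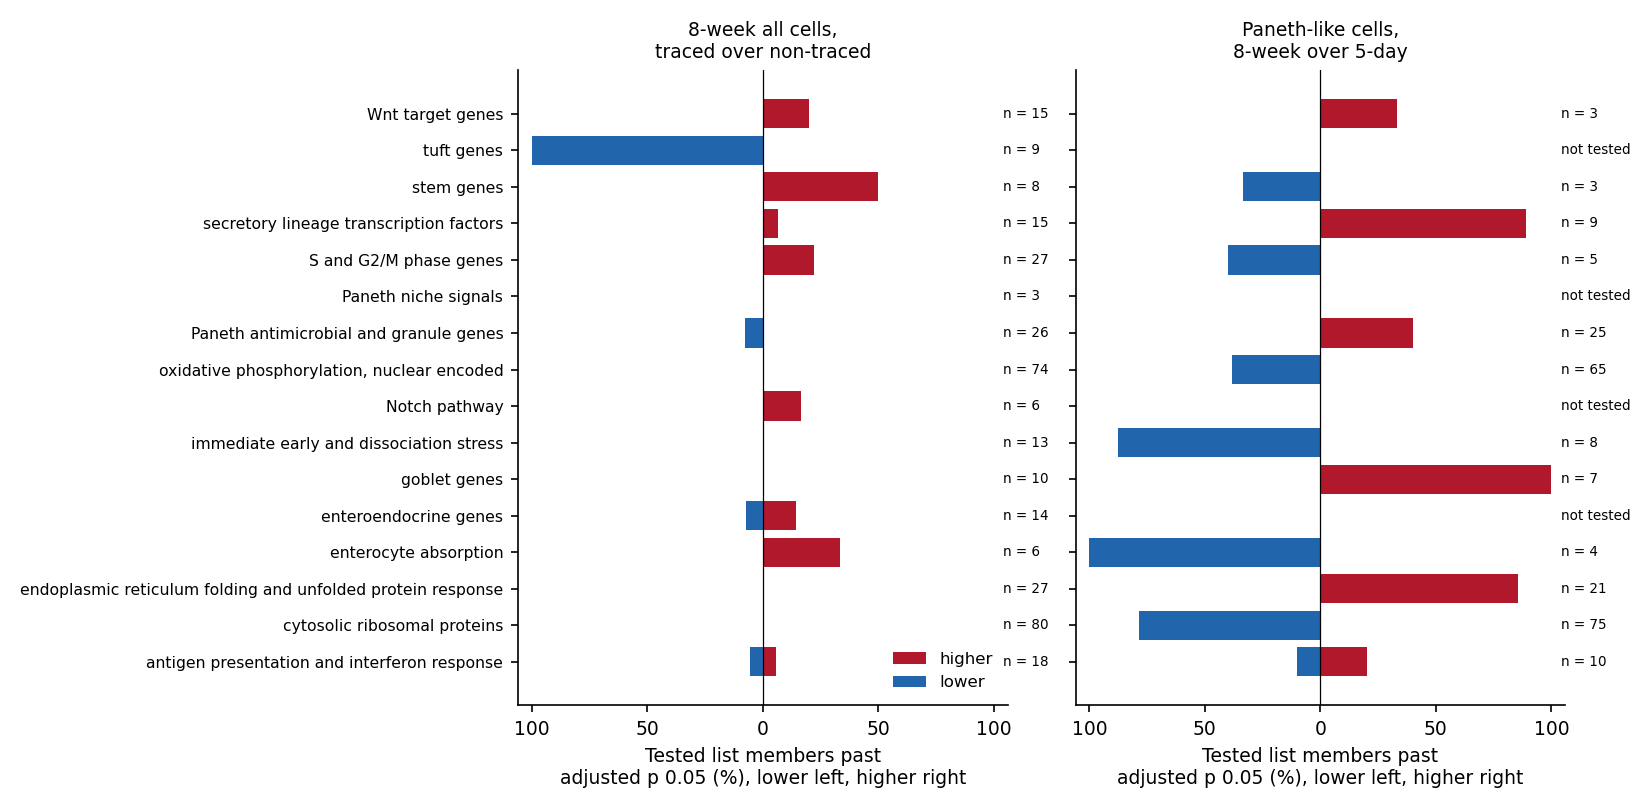
Percent of the tested members of each fixed list that passed the adjusted threshold, higher to the right and lower to the left, with n the number of members tested; left, all 8-week CD24+ cells, traced over non-traced, and right, Paneth-like cells, 8-week over 5-day. All 9 tuft genes were lower in the left panel, and 18 of 21 endoplasmic reticulum folding genes were higher in the right panel.

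Stem-like cells were then compared between the times, with all 5 5-day libraries rather than the 3 of the Paneth-like comparison (9, 12 and 10 cells at 8 weeks against 15, 13, 14, 7 and 17 at 5 days), a comparison added after the Paneth-like result. Antigen presentation genes rose (6 of 13), led by the MHC class II genes H2-Aa (1.73, SE 0.22, n = 3 and 5), H2-Ab1 (1.53) and H2-Eb1 (1.75) and the immunoproteasome subunit Psmb8 (1.33), and the Wnt targets Ccnd2 (1.22), Cd44 (1.17) and Ccnd1 (0.85) rose (3 of 10). Ribosomal protein genes fell (26 of 77), with Rpl31 (-1.65) and Rpl28 (-1.18), and 5 of 7 enterocyte genes fell, with Fabp2 (-2.19) and Prap1 (-1.49). The ribosomal count was 42 adjusted over the list alone and 17 with library sizes without Paneth antimicrobial genes. Oxidative phosphorylation genes (8 of 70) and, opposite to Paneth-like cells, goblet genes (2 of 4, Zg16 and Fcgbp, -2.10) fell as well. Over all classes, Zg16 was found in 58 of 68 cells of 5-day replicate 4, which the Paneth-like comparison left out. In the other 5-day libraries it was found in 23 of 63 (replicate 3) to 45 of 60 cells (replicate 5). Whether the goblet and enterocyte falls belong to the stem-like class was not tested. Only 3 of 20 endoplasmic reticulum folding genes rose, namely Pdia3 (1.22), Hspa5 (1.02) and Sec61a1 (0.87). With edgeR 280 of 2239 genes passed (136 higher, 144 lower), and 17.3% had no overlap between the groups, where chance gives 1 in 28. Camera gave adjusted p = 0.000291 for antigen presentation, 0.0042 for Wnt targets, 8.11e-10 for ribosomal proteins, 0.000157 for enterocyte genes, 1.65e-06 for oxidative phosphorylation and 0.0485 for goblet genes, each 0.186 with an estimated correlation. Without 8-week traced CD24+ replicate 2 the count was 175, and the stem-like cells of the 2 times lay mostly in different clusters.

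Of the 503 genes that changed in Paneth-like cells, 394 were tested in stem-like cells, where 334 (84.8%) had the same direction and 115 passed the same way, against 4 the other way. Within the 6 libraries of the Paneth-like comparison it was 327 of 382 (85.6%). Across the 1007 genes tested in both classes, which are not independent replicates, Pearson's r was 0.626 and Spearman's rho 0.589. The change with time was then compared between the classes in 1 model, added after the data had been examined. It differed for 35 of 1024 genes with edgeR (21 higher, 14 lower in Paneth-like relative to stem-like cells), including Guca2b (4.55, SE 0.77), Spink4 (2.28), Tff3 (2.16), the retrieval receptor Kdelr2 (2.14), Calr (2.04) and, lower, the inflammasome gene Nlrp6 (-3.32), Ccnd1 (-2.70), Stmn1 (-2.09) and Jun (-1.62). Of 20 endoplasmic reticulum folding genes 5 were higher, 6 adjusted over the list alone (adjusted p = 1.01e-08, and 0.0411 with an estimated correlation, but 0.0955 to 0.139 without any 1 of the 6 libraries). DESeq2 called 0 of these genes, against 180 at an unadjusted p under 0.05 in edgeR, and leaving out 1 library gave 8 (without 5-day replicate 5) to 58 (without 8-week traced CD24+ replicate 2).

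**Figure D5:**
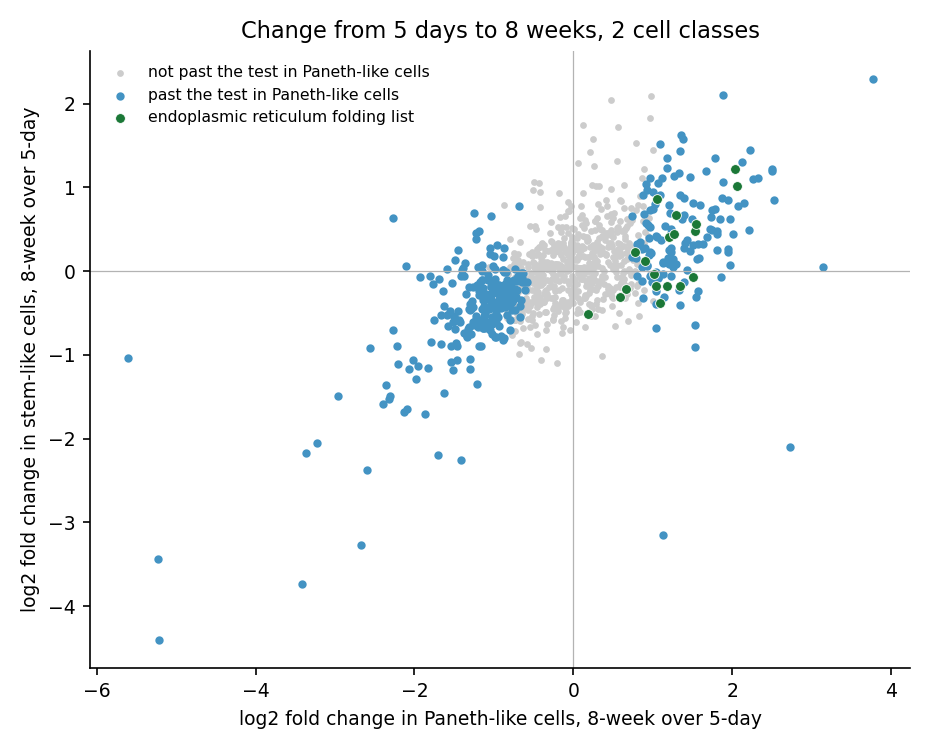
Fitted log2 fold change from 5 days to 8 weeks in Paneth-like cells (x axis) and in stem-like cells (y axis) for the 1007 genes tested in both classes, with the endoplasmic reticulum folding list in green. Of the 394 genes past the test in Paneth-like cells, 334 had the same sign in stem-like cells, and Hspa5 lies at 2.06 and 1.02.

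At 3 weeks each group was 1 library, so values are given without a test. Traced CD24+ cells were 29 goblet-like and 20 tuft-like of 62, and 0 of 62 were Paneth-like. That allows a share of up to 4.84% by the floor of 3 counts and up to 5.78% by the exact interval. The library labelled non-traced CD24+ had 0 Paneth-like of 50 cells, which allows up to 6.0% and 7.11%. These limits cover counting only. Cells were named by cluster, so a cell with Paneth transcripts in a cluster of another name was not counted, and 0 does not show that such cells were absent. Over all libraries, 79 of the 81 cells with a Paneth marker share of at least 5% were Paneth-like by cluster. Paneth antimicrobial and granule genes took 0.385% and 0.189% of the transcripts in these libraries, against 6.63% to 14.9% in the 8-week traced CD24+ ones. The hormone gene Sst was at 845 transcripts in the traced library and 0 in the other (at least 239-fold higher), the lectin Itln1 at 292 and 2 (124-fold, counting interval 33.9 to 1026), Defa24 at 636 and 6 (89.8-fold), Reg4 at 155 and 5 (26.3-fold), the protease Mmp7 at 119 and 5 (20.2-fold) and Chgb 7.38-fold higher. The antimicrobial lectin Reg3b (54.6-fold), the apolipoprotein Apoa4 (22 transcripts against 354), Reg1 (16.3-fold), the brush border phosphatase Alpi (15.1-fold) and Dmbt1 (14.7-fold) were lower in the traced library. Of the genes that separated traced from non-traced Paneth-like cells at 8 weeks, Mptx2, Scgb2b19, Pnliprp2, Defa23 and Gm21002 had at most 2 transcripts in each 3-week library. Summed over all cells, Cd177 (2.63-fold), Hmgcs1 (2.27-fold), Ms4a8a (2.07-fold), Gm10548 (1.80-fold), Fdps (1.58-fold) and AW112010 (1.52-fold) were higher in the traced 3-week library. Ckmt1 (1.74-fold), Prss32 (1.35-fold) and Anxa2 (1.30-fold) were lower in it. The counting intervals of Gm10548, AW112010, Prss32 and Anxa2 include no difference. With 0 Paneth-like cells there, these values do not bear on the change within Paneth-like cells. Cd24a, which encodes the sorted antigen, stood at 29.6 per 10000 transcripts in the traced library and at 5.44 in the other, and the combined table names the cells of the other library with YFP and without CD24. Since YFP marks traced cells, the 3-week values may compare traced cells with and without the gate.

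The 8-week traced library without the CD24 gate held 80 cells, of which 33 (41.2%, exact interval 30.4 to 52.8) were stem-like, 3 Paneth-like and 3 tuft-like. Enterocyte genes such as the bile acid carrier Fabp6 (26.3-fold) and Mep1b (11.4-fold), the goblet genes Zg16 (15.6-fold) and Clca3 (7.79-fold), and Apol10a (25.2-fold) were higher without the gate than in the mean of the 3 gated libraries. The gated levels ran from 1.54 to 157 CPM for Zg16, from 3.09 to 94.2 CPM for Clca3, from 1.54 to 8.68 CPM for Fabp6 and from 75.7 to 1122 CPM for Gcg, so these folds depend on the libraries in the mean. The hormone genes Gcg (at least 152-fold) and Sst (at least 134-fold), Neurog3 (23.5-fold) and Chgb (6.42-fold), and the Paneth genes Pnliprp2 (6.74-fold) and Mptx2 (3.33-fold) were lower. Sst was at 0 in 1 of the gated libraries. Alb (at least 56.2-fold) and Ahsg (at least 41.7-fold), which encode plasma proteins, were lower as well, with gated levels from 0 to 539 and from 0 to 402 CPM. Cd177 was close in both (77.2 CPM against 74.1 ± 23.7, SD, n = 3).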

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

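The tests of the CD24 gate label and of the class mix, of the library-wide difference between times, of the mix of states in the Paneth-like class and of other splits of the samples (except for stem-like cells) were chosen after the result was seen, as was the rule that an explanation is set aside only when a ratio's 95% interval lies on 1 side of 0.5, the 60% limit for shared direction, and both forms of the test of the endoplasmic reticulum list against stem-like cells.

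The library labelled 3-week non-traced CD24+ had a low level of Cd24a: traced minus labelled non-traced was 24.16 per 10000 transcripts at 3 weeks, while at 8 weeks every traced library lay below every non-traced one, by -21.69 to -16.18, a difference that was not tested. Its own level was 5.443, below the other CD24+ libraries (15.2 to 36.9) and inside the range of the libraries without the gate (3.74 to 6.06). Cells sorted without the gate are therefore a candidate explanation, and the combined table's name for these cells holds no CD24. That name also conflicts with the label non-traced, since YFP marks traced cells. If the name is right, the 3-week values compare traced cells with and without the gate. Its mix of classes remains open: over the 19 cells with a named class Cd24a was at 0.7456 of the level that the other CD24+ libraries give for those classes (interval 0.3105 to 0.9663). The classes differed: 2 tuft-like cells stood at 70.83 per 10000 transcripts against 76.01 in the other CD24+ libraries. The 5 goblet-like cells stood at 3.15 against 8.798, and 2 enteroendocrine-like cells at 5.868 against 15.38. The 10 enterocyte-like cells (0.4748) had only 1 cell (0.5847) to be compared with. A first form of this test over all 50 cells gave 0.2865 (0.0722 to 0.490), which would have set the class mix aside; it was replaced because the unnamed cells of the other libraries belong to other clusters. The share of tuft-like cells also went opposite ways, 28.26 percentage points higher in the traced library at 3 weeks and traced minus non-traced was -31.97 to -26.08 at 8 weeks, untested as well, and no biological explanation was tested.

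The change from 5 days to 8 weeks in Paneth-like cells coincides with differences in gate, sex and cluster. A library-wide difference may account for part of it, since 85.6% of the calls tested had the same direction in stem-like cells of the same 6 libraries (84.8% with all 5 5-day libraries), although the slope of the stem-like on the Paneth-like fold was 0.399 over these genes. For the endoplasmic reticulum folding list the values argue against such a difference, if alike in both classes, as the whole cause. The list mean of the Paneth-like minus stem-like log2 level was higher at 8 weeks than at 5 days by 1.283 (0.899 to 1.666 over libraries; without any 1 of the 6, the lowest limit was 0.77). The median change in stem-like cells was 0.184 of that in Paneth-like cells in the same 6 libraries (-0.128 to 0.336), and 0.102 with all 5 5-day libraries (-0.17 to 0.394). The stem-like cells of the 2 times also lay mostly in different clusters, so this contrast does not isolate a library-wide difference. An earlier form of this test asked that the list pass in every alternative with an estimated correlation and left the question open: adjusted p was 0.0411, 0.0451 with RLE factors, and 0.0955 to 0.139 without any 1 of the 6 libraries. That form was replaced after its values were seen, because leaving out a library kept the median of the difference between 1.21 and 1.42. Different Paneth-like clusters at the 2 times remain open for this list: its median over 18 genes was 1.194 in both clusters and 0.5 in the cluster of the 5-day cells, where 2 8-week libraries of 3 cells each were left and 14 of the 18 genes were higher, a ratio of 0.419 that meets the limit of 0.5 written before, with an interval of 0.154 to 0.544 that crosses it. Time after tracing, sex and gate stay open as untested explanations.

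The 24 genes that separated traced from non-traced Paneth-like cells at 8 weeks could reflect RNA of tuft-like cells, which were more numerous in the non-traced libraries. At the 0.858% share that 9 tuft markers give, tuft RNA accounted for a median of 0.008591 of the level of the 13 lower genes (0.000286 to 0.0174), which argues against it for these 13. RNA of other classes in the 11 higher genes, such as enteroendocrine RNA for Chgb, was not tested. A mix of cell states in the class is argued against as the whole cause by the fold changes at resolution 2, where a mixed cluster leaves the class: with no filter on low counts the median ratio to those reported was 0.818 over all 24 genes (0.792 to 1.021), all in the same direction. With the filter 17 of the 24 could be tested, at a ratio of 0.87 (0.76 to 0.981), and 1 gene passed there. With no filter 23 genes passed, 0 of them higher, against 11 higher as reported. The median pools 13 falls with 11 rises, so it does not speak for the rises alone. Nor was it a test of the mix of the 2 Paneth-like clusters. In the larger of them alone the median ratio was 1.002 over 23 genes, with 11 genes past the test (5 higher, 6 lower). No interval was computed for that ratio, so this mix was not set aside. Guca2a (-1.40), a leading gene of the goblet-like cells, and Lgals2 (-1.27) were among the 13 lower genes, named here after their values were seen. Goblet-like cells were more numerous in the traced libraries (7.96% against 0.595%). RNA leaked from them would thus raise Guca2a in the traced cells, the opposite of what was seen. A part for goblet-like cells inside the class stays open. The form over all 24 was added after the other was seen. Where 0 genes passed, the median ratio was 0.973 without traced replicate 3, 0.941 with at least 1500 transcripts per cell and 0.978 with a replicate block, which also leaves out traced replicate 3. Here too the genes had been chosen by their changes in mostly the same cells, so ratios near 1 were likely either way. They do not offset the loss of the calls. Tracing itself stays open as an explanation, and 3 against 2 libraries carry the comparison.

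Among 5-day libraries 4 of 70 gaps tested over 35 quantities were wider than Dixon's limit, where chance gives about 1 in 20 groups; Ghrl, Zg16 and Fabp1 were added to these quantities after replicate 4 was seen to stand apart. In replicate 4 Ghrl was at 31.8 per 10000 transcripts against 0.732 in the nearest library and was found in 63 of 68 cells, Zg16 was at 20.2 against 7.87, and the share of unnamed cells was 63.24% against 23.81%. Cd24a was at 6.065 in replicate 3 against 4.37 in the nearest.

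The change with time differed between Paneth-like and stem-like cells for 35 genes, where the highest of the other 9 splits of the 6 libraries gave 1. For Paneth-like against stem-like cells the real division gave 64 genes and the highest other 0, for Paneth-like against goblet-like cells 101 and 0. These 2 comparisons are paired within libraries: 4 of their 10 splits part all 3 pairs, the real one and 3 others with 0 genes each, while the other 6 put both sums of some libraries on 1 side. For 8-week against 5-day Paneth-like cells the values were 503 and 0. In these comparisons the splits are too few for a share under 0.05. For stem-like cells between the times, 1 of 56 splits, the real one, gave as many as 280 genes and the highest other gave 12. That is the smallest share that 56 splits allow, so chance is unlikely there but not excluded. The real split also divides the libraries by sex and gate.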

How the results depend on the processing

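The batch block, resolution 2 together with no filter, single Paneth-like clusters, leaving out the mixed cluster, variable genes over all cells, and all alternatives of the tuft-like, stem-like (between times) and Paneth-like minus stem-like comparisons were chosen after seeing the data. Of 3578 values of named called genes under the alternatives, 3115 kept direction and side of the threshold. Another 463 fell short of it in the same direction, and 0 turned. For traced against non-traced Paneth-like cells 144 of 340 fell short, and for Paneth-like cells between times 16 of 986. The genes had passed in the same data, and those named by size had no overlap between groups (or 1 direction in every library). Few turns were therefore possible, and that 0 turned is no test of the changes. Among called genes that are not named, 1 turned (Paneth-like against stem-like cells, at least 5000 transcripts). Where a count moved, the cause was not tested, except that single clusters and left-out libraries use fewer cells. Traced against non-traced Paneth-like cells (24 genes) gave 58 with no filter, 0 with at least 1500 transcripts, 1 at resolution 2 (23 there with no filter, 0 of them higher), 13 by marker share, 0 with a replicate block (which also leaves out traced replicate 3), 40 with a batch block, 11 in the larger cluster, and 0 (without traced replicate 3) to 79 without 1 library. All cells (371) gave 200 with DESeq2, 811 with no filter and 55 to 344 without 1 library. Paneth-like cells between times (503) gave 22 in the smaller cluster and 398 to 577 without 1 library; against stem-like cells (64), 105 with all counts and 45 to 71, with no value at 1500 transcripts or resolution 0.5; against goblet-like cells (101), 45 with DESeq2, 59 without the block and 58 to 115. Tuft-like cells (1) gave 0 with DESeq2, 2 with library sizes without Paneth genes and 0 to 11; stem-like cells between times (280) gave 175 to 287; the class difference with time (35) gave 0 with DESeq2 and 8 to 58. With an estimated correlation 0 lists passed in 7 of these comparisons and 1 in the class difference. Share differences that turned (percentage points) were, 8 weeks minus 5 days, goblet-like at 1500 transcripts (1.99), at resolution 2 (2.31) and without traced 8-week replicate 2 (1.29), and proliferating-like at 1500 (27.3) and 5000 transcripts (12.6); and, traced minus non-traced, enteroendocrine-like at 5000 (-1.96) and Paneth-like at resolution 2 (1.56). Over all left-out libraries share differences ran from -29.65 (tuft-like, traced minus non-traced, without traced 8-week replicate 2) to 25.11 (enteroendocrine-like, 8 weeks minus 5 days, without traced 8-week replicate 1). Of simulated 2-fold changes, 26.3% were recovered in 8-week Paneth-like cells.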

Other observations

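These values were chosen after the data had been examined and carry no test. A cluster of 35 cells, 31 of them from the library labelled 3-week non-traced CD24+ and led by Dmbt1, Clca4, Hmgb2, Ccdc34 and Top2a, stayed unnamed because 88.6% came from that library. Its members took 62% of that library's cells and 4.8% of the 3-week traced ones. A further unnamed cluster held 41 cells, all of 5-day replicate 4, with the goblet genes Zg16, Spink4 and Fcgbp, the enterocyte genes Fabp1 and Apoa1 and the hormone gene Ghrl among its leading genes. Another held 18 cells with a median of 18456 transcripts and was led by Dmbt1, Clca4 and Pycard, with the antigen presentation genes H2-Aa and Cd74 and the tuft gene Dclk1 further down. The tuft-like cluster that held 16 of the 20 tuft-like cells of the 3-week traced library drew 84.2% of its cells from it, just under the limit of 85% for a name.

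The larger Paneth-like cluster held 55 cells with Spink4, Muc2 and Guca2b beside the defensins among its leading genes, and the smaller 30 cells led by Defa17, Gm15284, Gm14851 and Ang4, with Mptx2 and Pnliprp2. In the 8-week traced CD24+ libraries 27 cells lay in the larger and 7 in the smaller cluster, and in the non-traced ones 25 and 2. The 21 Paneth-like cells of the 5-day libraries all lay in the smaller. A class defined by marker share held 81 cells, 79 of them Paneth-like by cluster, with 27 cells within a factor of 2 of its limit.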
